A study of Homo sapiens with 4 samples.

How the data were processed

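Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map c-MYC binding in UACC-812, a breast cancer cell line. Per the labels, 1 derived line overexpresses c-MYC and the other is a flag line, and each gave 1 ChIP library and 1 input library, 4 libraries in all. Each library was its own group, so no group had replicates and values are compared between libraries, not conditions. ChIP and input of each line form 2 pairs, for which an exact sign-flip permutation test cannot go below p = 0.5. The labels give a c-MYC antibody for both ChIP libraries. For both input libraries they give an RNA polymerase II antibody, which conflicts with the titles that call them input, and the titles were followed here.

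Per the labels' protocols, cells were fixed with formaldehyde, nuclei were isolated and libraries were made with an Illumina DNA kit. The submitters' processing notes name CASAVA 1.4, cutadapt 1.19, Bowtie2 2.3.0 and MACS2 2.1.1, with the human build GRCh38, also called hg38. Whether a control library entered the peak calling, which threshold was used and how reads with several genomic matches were treated is not given in the sources used here. Each file lists the intervals called in 1 library. Per the file headers, the deposited signal of an interval is its pileup at the summit, a whole number. The authors' fold enrichment is a ratio over a background that the headers do not define. It was not ChIP pileup over input pileup. At NME7 the flag line ChIP list gave a fold of 18.9 with a pileup of 43 in both ChIP and input. At MTCO3P12 the c-MYC line ChIP list gave a fold of 3.38 with pileups of 110 in ChIP and 447 in input. Fold is therefore not read as enrichment over input, and regions high in both libraries can be listed in both. The deposited -log10 values are those of the caller's p and q. The deposited peak score was the whole part of 10 times the -log10 q in all 391 intervals. The deposited distance to the TSS (transcription start site) and the nearest gene come from an Ensembl annotation whose release is not given in the sources used here. Because the pileups carry no stated scaling and the total reads of each library are not given in the sources used here, the sequencing depth is unknown, and fold and q were used only to describe, rank or filter intervals within a list.

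Coordinates are 1-based on GRCh38, as in the files. Gene positions for the fixed gene lists and for TINCR, EGFR and ERBB2 came from the RefSeq table of GRCh38.p14. Of the 174 nearest gene names in the files, 111 were found in that table by symbol, and 107 of these started within 100 kb of the position the files give. Intervals of 2 lists were counted as shared at an overlap of at least 1 bp, and overlapping intervals of all lists were joined into 205 regions. Expectations and one-sided p-values came from a positional permutation test, 1000 random placements of the same interval widths, within the same chromosome for overlaps, promoters and gene lists and over chromosomes 1 to 22, X and Y for the chromosome counts. No genome sequence was used here, so placements ran from the first base to the last RefSeq gene end of each chromosome and did not leave out assembly gaps. The expectation takes no account of repeats or of how well reads can be placed. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Fisher's exact tests between lists were two-sided and compare libraries, not conditions. Adjusted p is Benjamini-Hochberg.

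The promoter share counted intervals whose deposited distance to the nearest TSS was at most 1 kb and whose nearest gene was protein coding or a long non-coding RNA (lncRNA). The RefSeq table used here gives no strand, so the random expectation was computed for the ends of either side of coding and lncRNA genes, with the observed count measured in the same way. The planned count of E-box motifs was not run, because it needs the genome sequence. The planned overlap of input intervals with MYC exons was counted for the whole gene, so exon positions were not compared. The 15 gene lists, holding 405 genes of which 404 matched a RefSeq symbol, were fixed before the data were examined, as were the tests, the alternatives and the rule for the genes named. That rule takes MYC, TINCR, EGFR and ERBB2. It also takes, in each list, the 10 intervals of highest fold and up to 20 genes with an interval within 1 kb of their TSS in order of -log10 q. Last, it takes genes of a fixed list with an interval in the gene body or its 5 kb flank in a ChIP list and none in the input of the same line. Classes of nearest gene (mitochondrial gene copies, small nuclear RNA genes and others) were chosen after the values were seen. Mitochondrial gene copies were taken by name and comprise pseudogenes of mitochondrial genes and the MTRNR2L genes, which the files annotate as protein coding.

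The alternatives were a fold of at least 5, a q of at most 0.01, a TSS window of 500 bp or 5 kb, protein coding genes only, removal of intervals also in the input, a reciprocal overlap of 50%, intervals within 500 bp, merging within 10 kb, gene bodies alone, and a window of 100 kb around TINCR and EGFR. A pileup of at least 20, RefSeq gene ends for the promoter share and the reference regions for the MYC pileup were added after the data were seen. The overlap and gene list code was tested on simulated data: 60 of 60 overlaps planted among the 161 flag line ChIP intervals were found, as with bedtools 2.31.1, and 5 planted MYC target genes gave p = 0.005 in the positional permutation test, while 2% of 100 unplanted simulations fell below 0.05. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.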

Results

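c-MYC ChIP-seq was carried out in derivatives of UACC-812, a breast cancer line with ERBB2 amplification, to examine c-MYC binding in a line overexpressing c-MYC and in a flag line. The series names MYC, the lncRNA TINCR and the receptor gene EGFR as parts of a loop. The c-MYC line gave 25 intervals in its ChIP list and 86 in its input list, and the flag line gave 161 and 119. The median interval length was 529 bp in the c-MYC line ChIP list, 520 bp in its input, 441 bp in the flag line ChIP list and 506 bp in its input. The lowest pileup at which an interval was listed was 10, 13, 8 and 11 in the same order. With 1 library per group there was no replicate spread against which to set any difference, and the total read number behind each list is unknown.

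The MYC gene itself, which encodes the transcription factor under study, carried intervals in all 4 lists, including both inputs. Each list held a pair of intervals there. In the c-MYC line ChIP list they lay on chromosome 8 at 127738111 to 127739154 and at 127740262 to 127741096, inside the MYC gene (127735434 to 127741434 in the deposited annotation), and were annotated as ends of MYC transcripts. Their deposited distances of 2038 and 4085 bp run from the interval centre to a TSS at 127736594, which lies 1160 bp inside the gene. No list held an interval in the first part of the gene or in the 1107 bp between these intervals. The edges were close between lists: over the 4 libraries, the start of the first interval varied by 102 bp and its end by 62 bp, and the second by 32 and 54 bp.

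As deposited, the pileup at MYC was higher in ChIP than in input in the c-MYC line and slightly lower in ChIP than in input in the flag line. It was 596 and 581 at the first and second interval in the c-MYC line ChIP library, against 163 and 146 in the input of that line. In the flag line it was 509 and 504 in the ChIP library and 566 and 566 in the input. Within its own list, the MYC pair had the highest -log10 q of all intervals in the c-MYC line ChIP list. It ranked 4 and 8 in the c-MYC line input and 2 and 3 in both flag line lists. The fold over the caller's background stayed between 6.46 and 7.69 in the 4 lists. These pileups are not scaled for depth. Relative to the 22 other regions listed in all 4 lists, ChIP over input at MYC was 10.6 in the c-MYC line and turned to 1.41 in the flag line, or 1.04 with the 15 of them not nearest a copy of a mitochondrial gene.

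**Figure D1:**
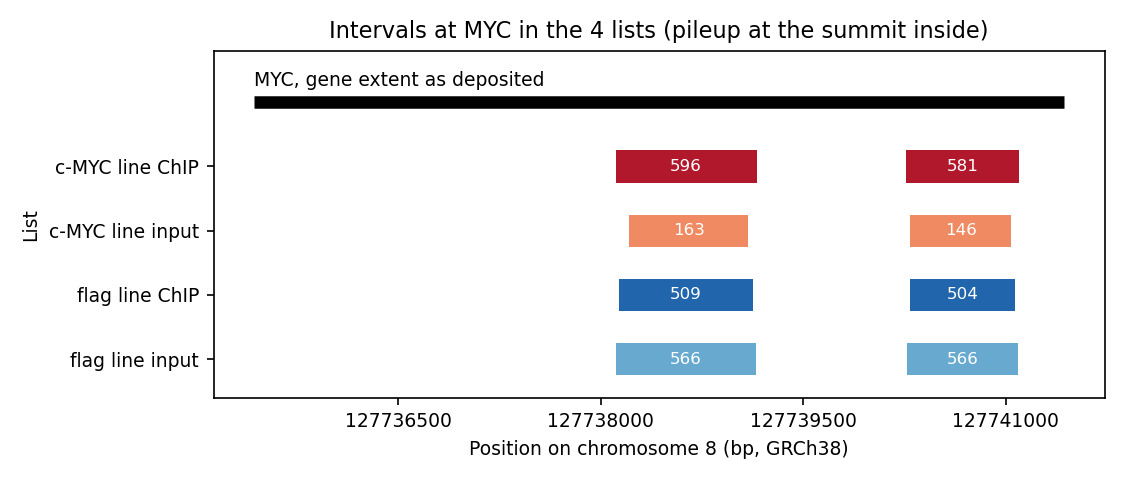
Intervals at MYC on chromosome 8 (horizontal axis, bp, GRCh38) in each of the 4 lists (rows), drawn to scale under the deposited extent of the gene (black bar), with the pileup at the summit written in each. The same pair of positions is listed in all 4 libraries, with the lowest pileups (163 and 146) in the c-MYC line input.

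Which c-MYC line ChIP intervals were absent from the input of the same line was asked next. None were: 25 of 25 overlapped an input interval (100%, 95% interval 86.3 to 100%), where random placement of the input intervals gave 0.002 on average (positional permutation test, one-sided, p = 0.001, the smallest that 1000 placements can give). All 25 were also in the flag line ChIP list, and 24 were in the flag line input (96%, 95% interval 79.6 to 99.9%). The exception was an interval on chromosome 17 from 21976202 to 21976723 nearest the pseudogene ABBA01006766.2. A reciprocal overlap of 50% left 23 of the 25 shared with the c-MYC line input.

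The nearest gene of most c-MYC line ChIP intervals was a pseudogene or a non-coding gene. Coding genes were nearest in 6 of 25 (24%, 95% interval 9.36 to 45.1%), apart from MTRNR2L1, a mitochondrial gene copy annotated as protein coding. These were MYC, KCNE1B, PYY and EMB. The regions nearest KCNE1B and EMB lay outside any RefSeq coding or lncRNA gene. The highest fold of the list, 18.5, was on chromosome 3 at 93470165 to 93470968. This intergenic interval lay 373198 bp from the nearest TSS, that of the small nuclear RNA pseudogene RNU6-488P. This region also had the highest fold in the other 3 lists. The rest of the 10 highest lay nearest CU634019.3, LINC01691, KCNE1B, AC140113.4, the DUX4-like pseudogene DUX4L20, SNX18P25 and the microRNA gene MIR4485. PYY (inside the gene, which encodes the gut hormone peptide YY) and AC090531.1 (inside PDZRN4) completed them. Their deposited distances to the TSS ran from 302 bp at MIR4485 to 3603143 bp at LINC01691. KCNE1B was 96459 bp away, CU634019.3 120996 bp and AC140113.4 122053 bp. All 10 were listed in each of the other 3 libraries. Nuclear copies of mitochondrial genes were the nearest genes of 7 intervals (28%, 95% interval 12.1 to 49.4%). Of these, 6 were at pseudogenes, among them MTND2P28, MTCO3P12, MTND5P11, MTND4LP30 and MTND3P19, and 1 was nearest MTRNR2L1. In the other lists such copies, of which 10, 13 and 14 were pseudogenes and the rest coding MTRNR2L genes, took 12 of 86 intervals (14.0%) in the c-MYC line input, 14 of 161 (8.70%) in the flag line ChIP list and 17 of 119 (14.3%) in the flag line input.

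**Figure D2:**
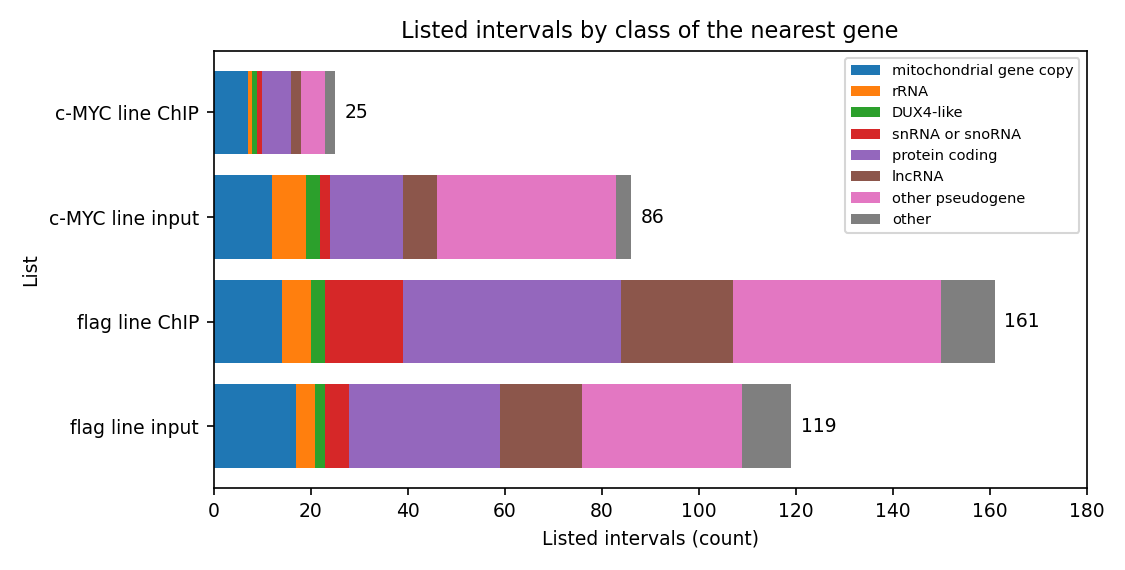
Number of listed intervals (horizontal axis) in each of the 4 lists (rows), coloured by the class of the nearest gene. The c-MYC line ChIP list is the shortest with 25 intervals, and intervals nearest small nuclear or nucleolar RNA genes number 16 in the flag line ChIP list against 5 in the flag line input.

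In the flag line, 98 of the 161 ChIP intervals were also listed in the input (60.9%, 95% interval 52.9 to 68.5%), against 0.004 at random placement (positional permutation test, one-sided, p = 0.001). The other 63 had a median pileup of 13, against 22 for those shared with the input. After the chromosome 3 interval, the highest folds were nearest RAP2C (chromosome X, 132276802 to 132277268, inside RAP2C-AS1, 57555 bp from the TSS) and NME7 (chromosome 1, inside the gene). Next came CDH11 (chromosome 16, 65124558 to 65125024, 499 bp upstream of a TSS of this cadherin gene) and AC004160.2 (chromosome 7, inside THSD7A). HSP90B3P, CU634019.3, AC108676.1, LINC01691 (3603257 bp from the TSS) and ZFYVE16 followed. All 10 were in the flag line input as well, at similar pileups. These were 49 and 50 in ChIP and input nearest RAP2C, 43 and 43 at NME7, 47 and 53 at CDH11 and 53 and 57 nearest AC004160.2. In the flag line input, the 10 highest folds also took in AC090531.1, MTND2P18, CDY3P and MLPH, a melanosome transport gene. The 10 highest folds in the c-MYC line input included intervals nearest MLPH, DCUN1D4 (735596 bp from the TSS), AL512658.1 and AL590623.1. These were not in the c-MYC line ChIP list but were in both flag line lists.

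Between the lines, 25 of the 161 flag line ChIP intervals were in the c-MYC line ChIP list (15.5%, 95% interval 10.3 to 22.1%), and 59 were in the c-MYC line input (36.6%, 95% interval 29.2 to 44.6%). Among intervals with a pileup of at least 20 in both lists, these shares were 29.0% and 56.5%. Of the 205 regions formed from all lists, 24 were in all 4. A further 51 were in both flag line libraries and in neither c-MYC line library, and 51 were in the flag line ChIP list alone. The c-MYC line input alone held 23 and the flag line input alone 17. No region was listed in the c-MYC line ChIP library alone.

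**Figure D3:**
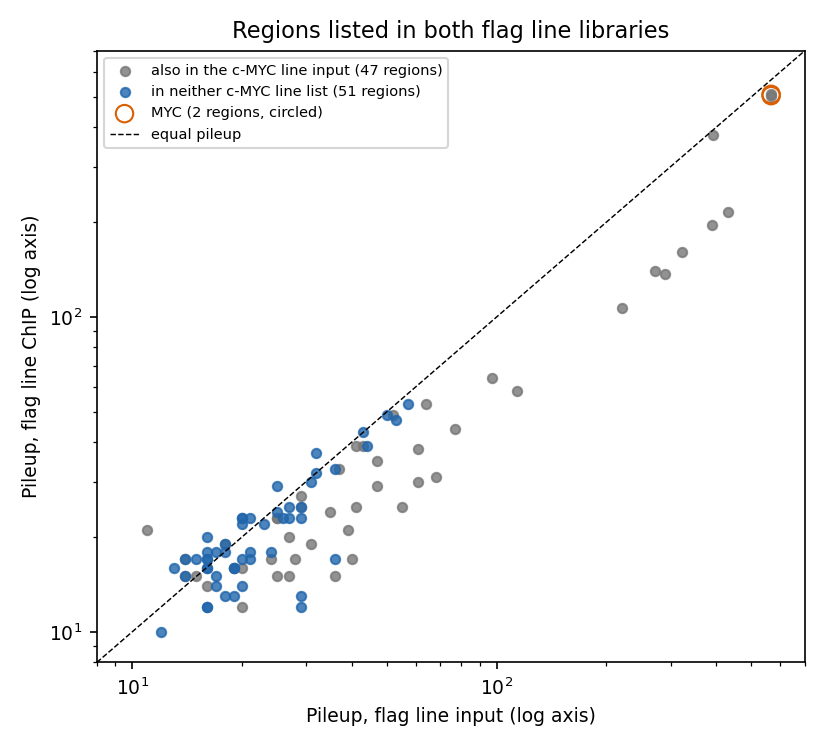
Pileup of the 98 regions listed in both flag line libraries, input on the horizontal and ChIP on the vertical axis (both logarithmic), grey where the c-MYC line input lists the region and blue where neither c-MYC line list does; the dashed line marks equal pileup. The 51 blue regions lie near that line, with a median ChIP over input ratio of 0.930.

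Few intervals lay at the start of a gene, where c-MYC is known to bind. In the c-MYC line ChIP list, 0 of 25 were within 1 kb of the TSS of a protein coding or lncRNA gene (95% interval 0 to 13.7%). The share was 2 of 86 in the c-MYC line input (2.33%), 7 of 161 in the flag line ChIP list (4.35%, 95% interval 1.77 to 8.75%) and 5 of 119 in the flag line input (4.20%). Among the flag line ChIP intervals absent from the input it was 7.94%. With a window of 5 kb the shares were 12% and 9.30% in the c-MYC line ChIP and input lists and 14.3% and 15.1% in those of the flag line. No difference was detected between ChIP and input in the flag line (Fisher's exact test, two-sided, p = 1, adjusted p = 1 over 4 comparisons) or in the c-MYC line (Fisher's exact test, p = 1), or between the ChIP lists (Fisher's exact test, p = 0.596). Against the ends of RefSeq coding and lncRNA genes, the c-MYC line ChIP list had 2 of 25 intervals within 1 kb (8%) where random placement gave 1.27 (positional permutation test, one-sided, p = 0.362). They were nearest MTND2P28 and MIR4485 and were listed in all 4 libraries. The c-MYC line input had 3 of 86 (3.49%) where 3.88 were expected (same permutation test, p = 0.753; against ChIP, Fisher's exact test, two-sided, p = 0.314, adjusted p = 0.628 over 4 comparisons). By the same measure, the flag line ChIP list had 10 intervals within 1 kb where random placement gave 7.27 (positional permutation test, one-sided, p = 0.189). The flag line input had 2 where 5.10 were expected (same permutation test, p = 0.965), 1.68% against 6.21% in ChIP (Fisher's exact test, two-sided, p = 0.0774, adjusted p = 0.310 over 4 comparisons).

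The genes at those starts were few. In the flag line ChIP list they were SOX2, a stem cell transcription factor, CDH11, REXO4, AC009950.1, AL355297.4 and BX284668.6. The SOX2 interval (chromosome 3, 181712479 to 181713015, in the exon of this gene and 823 bp from its TSS) had a pileup of 47 and a fold of 14.1 and was in no other list. A CDH11 interval and AC009950.1 were also in the flag line input, which further had AMY2A, MTRNR2L8 and MTRNR2L12. In the c-MYC line input they were MTRNR2L12 and CASC19, a lncRNA gene on the same chromosome as MYC, with a pileup of 52 and a fold of 2.80 at 127219067 to 127219572. Counting genes of every class, intervals within 1 kb of a TSS numbered 7, 16, 32 and 20 in the c-MYC line ChIP, c-MYC line input, flag line ChIP and flag line input lists, of which 6, 10, 12 and 12 were at mitochondrial pseudogenes. The flag line ChIP list also had RNU5D-1 and RNU5A-8P, small nuclear RNA loci, among its 20 highest.

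TINCR and EGFR carried no interval within 10 kb, or within 100 kb, in any of the 4 lists. TINCR (chromosome 19, 5558167 to 5567953) had no interval on its chromosome in either c-MYC line list, and in both flag line lists the nearest was 40.9 Mb away, near PNMA8C. EGFR (chromosome 7, 55019017 to 55211628) had no interval on its chromosome in the c-MYC line ChIP list, and the nearest in the other 3 lay 7.14 Mb away. ERBB2 (chromosome 17, 39688094 to 39728658) also had none within 100 kb, and neither input held an interval from 39404285 to 40357643, the stretch spanned by the fixed list of genes around ERBB2. Absence from a list of called intervals does not show that the protein was not bound.

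Of the 15 gene lists, MYC targets had 1 gene of 71 with an interval, NOP58, a nucleolar protein gene, and neural genes had 1 of 18, DLG2, a synaptic scaffold gene. Both were listed in the flag line ChIP library and in the flag line input, with pileups of 22 and 23 at NOP58 and 37 and 32 at DLG2. Random placement gave 0.112 MYC target genes and 0.651 neural genes in the flag line ChIP list (positional permutation test, one-sided, p = 0.105 and 0.486; adjusted p = 1 for both over 60 tests). The remaining 13 lists had no gene with an interval in any list: ribosomal proteins, cell cycle, glycolysis, histone genes, EGFR and ERBB signalling, luminal breast markers, basal and mesenchymal markers, epidermal differentiation, and 5 lists of regions often amplified in breast cancer on chromosomes 8, 11, 17 and 20. No gene of a fixed list had an interval in a ChIP list and none in the input of the same line.

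Intervals were spread over 13 chromosomes in the c-MYC line ChIP list, 21 in the c-MYC line input and 24 in both flag line lists. Chromosome 17 held 8 of the 86 c-MYC line input intervals (9.30%, 95% interval 4.10 to 17.5%) where 2.34 were expected from chromosome length (positional permutation test, one-sided, unadjusted p = 0.002, adjusted p = 0.096 over 96 tests). It held 11 of the 161 flag line ChIP intervals (6.83%) where 4.31 were expected (same permutation test, unadjusted p = 0.004, adjusted p = 0.096). Chromosome 5 held 6 of the 25 c-MYC line ChIP intervals where 1.47 were expected, and chromosome Y 6 of the c-MYC line input intervals where 1.58 were expected (same permutation test, unadjusted p = 0.004 and 0.003, adjusted p = 0.096 for both). The test counts neighbouring intervals as independent, which they need not be. On chromosome 5, those nearest MTND5P11 and MTND4LP30 lay together between 134925181 and 134928581. No chromosome passed an adjusted 0.05, with or without merging within 10 kb, and 1000 placements cannot take a lone chromosome below 0.096. At an unadjusted 0.05 the numbers were 3, 6, 1 and 2 in the c-MYC line ChIP, c-MYC line input, flag line ChIP and flag line input lists.

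**Figure D4:**
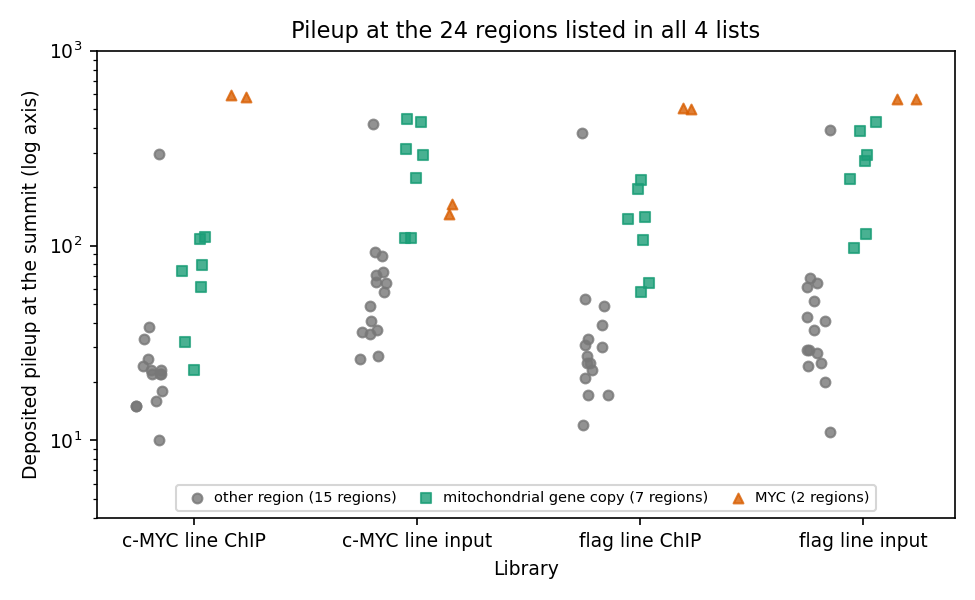
Deposited pileup at the summit (vertical axis, logarithmic, not scaled for depth) of the 24 regions listed in all 4 lists, by library (horizontal axis); triangles are MYC, squares regions nearest nuclear copies of mitochondrial genes and circles the other regions. MYC lies above all others in 3 libraries and below most of the squares in the c-MYC line input.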

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

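The tests of explanations in this part were all chosen after the MYC values were seen, and with 1 library per group the differences between the lines were not tested. The pileup at MYC stood apart because the lines differed in its direction between ChIP and input: the log2 ratio, averaged over both intervals and without adjustment, was 1.93 in the c-MYC line and -0.16 in the flag line. The number of listed intervals also went opposite ways, with ChIP minus input at -61 in the c-MYC line and 42 in the flag line.

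Pileups are not scaled between libraries, so the 22 other regions in all 4 lists were used to set a relative depth. Their median ChIP over input ratio was 0.361 in the c-MYC line and 0.635 in the flag line, and at MYC the adjusted ratio became 10.6 in the c-MYC line (9.44 to 14.0 with the quartiles of those regions) and 1.41 in the flag line (0.991 to 1.77). With the 15 regions not nearest a mitochondrial gene copy, called nuclear regions here, as reference, it was 9.92 and 1.04. Copies were taken by gene name alone, so the 15 can still hold some. Among them is the region nearest MIR4485 (chromosome 11, 10507704 to 10508394). It lies close to the flag line input interval nearest MTRNR2L8, at 10508999 to 10509281. The adjustment assumes that the antibody neither enriches nor depletes the reference regions. The quartiles understate their spread: the 22 ChIP over input ratios ran from 0.211 to 0.815 in the c-MYC line and from 0.456 to 1.91 in the flag line. All 22 also had to be listed in the short c-MYC line ChIP list, a selection that the adjustment does not correct for.

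A uniformly amplified stretch around the gene would by itself set no edges inside it. No edge of the MYC pair varied by more than 102 bp over the 4 lists. Random placement of the same widths within the gene gave a median of 2485 bp (permutation test, one-sided, p = 0.001). That p is the smallest that 1000 placements can give. Any region listed at the same place in all 4 libraries would give a small p, so this test cannot decide on amplification. Extra copies of the whole gene could add to the height of the pair, which was not tested. Carry-over of DNA from the c-MYC line input into the flag line libraries would leave more MYC in the former. The ratio of c-MYC line input over flag line input was 0.188 adjusted with the 15 nuclear regions. It was 0.231 with all 22 and 0.254 with the mitochondrial gene copies. These ratios bear on the c-MYC line input alone. Carry-over from the c-MYC line ChIP library, with pileups of 596 and 581 at MYC, was not tested. A MYC coding sequence outside its gene, such as a vector insert, would give both intervals nearly the same pileup at any level. The largest ratio between them within a library was 1.12, so this remains a candidate explanation. Other sources of extra MYC DNA could give the same, so near-equal pileup cannot tell them apart. No list held an interval in the first part of the gene or in the 1107 bp between the pair. Whether the pair lies on exons was not tested, and coverage outside listed intervals is not given in the sources used here. Whether extra MYC DNA sat in the cells of both lines or entered the libraries otherwise, and whether the c-MYC line excess in ChIP comes from binding to it, stays open.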

How the results depend on the processing

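The settings for the MYC pileup, the pileup floor of 20 and RefSeq gene ends were chosen after the data were seen. Of the 121 alternative values, 100 stayed within the 95% interval, the quartile range or 1.5 times the main count, among them all 36 planned ones for the overlaps between lists. With ChIP and input of each line as 2 pairs, a test added later, the difference in the number of intervals gave p = 1 (exact sign-flip permutation, two-sided, smallest possible p = 0.5). The planned E-box counts were not run, and removing input intervals left no c-MYC line ChIP interval for a promoter share. Depth limits every count here, since an interval under a list's floor is not seen. For each change below the cause was not tested, unless it is a wider or narrower window by construction. A TSS window of 5 kb gave promoter shares of 12% in the c-MYC line ChIP list, 9.30% in the c-MYC line input, 14.3% in the flag line ChIP list and 15.1% in the flag line input. Without intervals of the input, the flag line ChIP share was 7.94%. With 1 kb around gene ends, 0 fixed-list genes were left in both flag line lists. Merging within 10 kb joined the MYC pair to 1 interval in both inputs. With a pileup of at least 20 in both lists, the share of c-MYC line input intervals in the flag line ChIP list was 47.9%. For flag line ChIP intervals it was 29.0% in the c-MYC line ChIP list, 56.5% in the c-MYC line input and 83.9% in the flag line input. For flag line input intervals it was 57.3% in the c-MYC line input and 69.3% in the flag line ChIP list. The log2 MYC ratio of ChIP over input without adjustment reversed in the flag line, to -0.16, and was 1.93 in the c-MYC line. With mitochondrial gene copies as reference it was 0.83 and 3.92. For c-MYC line over flag line, it was -1.88 unadjusted and -1.98 with mitochondrial gene copies for the inputs, and 0.22 and 1.08 for the ChIP libraries.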

Other observations

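All patterns and tests in this part were chosen after the patterns were seen. The flag line ChIP list held 9 intervals within 1 kb of the TSS of a small nuclear or nucleolar RNA gene, and the other 3 lists held 0. They lay 113 to 436 bp from the start of RNU5A-1, RNU5D-1, RNU5E-1, RNU5F-1 and RNU5A-8P (U5 genes and a copy), RNU11 and RNU4ATAC (minor spliceosome), RNVU1-6 and SNORD118. The share was 9 of 161 (5.59%) against 0 of 119 in the flag line input (Fisher's exact test, two-sided, p = 0.0115, for a class picked after it was seen). Pileups were low, 8 to 15.

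At such pileups, missing an interval in the input may come from the floor of the list. Of 57 other flag line ChIP intervals with the same pileups, 18 were in the flag line input (31.6%), against 0 of the 9 (Fisher's exact test, two-sided, p = 0.100); since 0 is the lowest count there can be, 9 intervals are too few for this test to exclude the floor. RNA polymerase II transcribes these genes, and the labels name a polymerase II antibody for the inputs, so a mislabelled antibody in the flag line ChIP library could be asked about. No excess of its intervals near ends of coding and lncRNA genes was detected over random placement (positional permutation test, one-sided, p = 0.189). Their share, 6.21%, was above the 1.68% of the input (Fisher's exact test, two-sided, p = 0.0774). That count reuses the pattern, since it includes intervals at RNU11, RNVU1-6, SNORD118 and RNU4ATAC. The share therefore cannot speak for a polymerase II antibody, and weak enrichment at the strongest genes alone would leave it low. These explanations cannot be told apart with 1 library.

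The 51 regions in both flag line libraries and in neither c-MYC line library were spread over 19 chromosomes, 23 of them inside a coding or lncRNA gene, among them THSD7A, NME7, LIPA, DLG2, XPC, NR3C1 and ZFYVE16. Lower depth of the c-MYC line input could hide them. Scaled by the lowest ratio of the 15 nuclear regions listed in all 4 libraries (1.07), 32 of the 51 would reach a pileup of at least 20 there, where 15 intervals were listed at 20 or below, which argues against depth for those. Antibody-dependent binding in the flag line would raise ChIP over input. Their median ratio of 0.930 was 1.08 times that of the nuclear regions (permutation test, two-sided, p = 0.265). Both sets were picked for being listed in the flag line input too, which leaves out regions high in ChIP alone. The ratio therefore cannot decide on antibody-dependent binding. A difference in DNA between the lines or in library preparation stays open and untested.

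The 7 regions nearest mitochondrial gene copies had lower ChIP over input ratios in the median than the 15 nuclear regions in both lines, at 0.252 against 0.385 in the c-MYC line (exact permutation test, two-sided, p = 0.00141, adjusted p = 0.00281 over 2 comparisons) and 0.504 against 0.862 in the flag line (same exact test, p = 0.0119, adjusted p = 0.0119). The ranges overlapped, at 0.211 to 0.294 against 0.259 to 0.815 in the c-MYC line and 0.472 to 0.660 against 0.456 to 1.91 in the flag line. Neighbouring regions are not independent. The classes rest on gene names and may not be cleanly separated, since the 15 include the MIR4485 region close to MTRNR2L8. Without the region nearest MTRNR2L1, which is annotated as coding, the medians of the 6 pseudogene regions were 0.262 and 0.503. The fold at MYC hardly varied between 6.46 and 7.69 while the pileup varied from 146 to 596, and the background implied by pileup and fold was 22.8 to 77.8 there against list medians of 1.84 to 5.18.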
